A study of Danio rerio with 12 samples.

How the data were processed

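Polyadenylated RNA was sequenced from whole zebrafish embryos at 2, 4 and 6 hours post fertilization (hpf), in control embryos and in embryos labelled as homozygous for a Ddx3xb mutation. The labels give 12 samples, 2 per genotype and time point. RNA was extracted with TRIzol, messenger RNA was purified on Dynabeads and libraries were made with the KAPA Stranded mRNA-Seq kit, per the labels' protocols. Cutadapt 1.13, Trimmomatic 0.36, HISAT2 2.0.5, SAMtools 1.9 and the genome build Zv9 are named, with no roles, per the submitters' processing notes. The counting tool, the gene annotation and the use of strand in counting are not given in the sources used here. The series text calls the replicates biological; no label says how many embryos or which clutches went into each library.

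The values are RPKM (reads scaled by gene length and by library size), which the authors deposited as 6 tables, 1 per genotype and time point, each with 1 value for each of 33737 Ensembl gene IDs. Each table thus holds 1 value for its group of 2 samples, and values are given here as the authors' group values without a standard deviation. Tables were assigned to groups by the genotype and hour in their names, each of which matches 1 group in the labels. The planned test, a moderated linear model with the 12 libraries, could not be run on 1 value per group, so no p-value is given anywhere and differences are described by size; the plan named this fallback before the data were examined.

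Although the tables hold group values, low values were found to fall on a grid set by 2 libraries. A gene's value times its length equals a whole number of reads times the worth of 1 read in one library plus the same for the other, which is what a plain mean of 2 libraries gives. Starting step sizes were found by inspection and then refined by fit. For 7612 genes exactly 1 gene length satisfied all 6 tables, against 0 genes after each value had been moved at random by up to 0.5%. Under the assumption of a plain mean, the recovered depths were 55.2 and 49.7 M reads for the libraries of control embryos at 2 hpf, 53.8 and 50.3 M at 4 hpf and 40.9 and 37.8 M at 6 hpf. Those of mutant embryos were 62.9 and 58.1 M at 2 hpf, 39.6 and 38.8 M at 4 hpf and 73.0 and 41.5 M at 6 hpf. Which of each pair is replicate 1 cannot be read from the values. On simulated tables of 33737 genes the procedure returned 98.4% of lengths correctly, and a spread between libraries of 0.882 where the true value was 0.881. The simulation took plain means of 2 libraries and the same starting step sizes as given, so it checks neither of these. Depth and gene length are fixed only up to a common factor, which was chosen by the share of even gene lengths.

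The reads recovered in this way give the spread between replicates for genes with 20 to 150 reads over both libraries, and no others. The log2 ratio between the 2 libraries had a spread (scaled median absolute deviation) of 0.83, 0.76 and 0.76 in controls at 2, 4 and 6 hpf, over 2005, 2968 and 2177 genes, and of 1.00, 0.89 and 0.99 in mutants, over 2151, 2231 and 2793 genes. The spread of well expressed genes could not be recovered, so it is unknown for nearly every gene named in the text. These reads were not used for any count test.

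Values were compared as log2(RPKM + 1), which understates the differences of low genes. A gene was kept if its RPKM was at least 1 in at least 1 of the 6 tables, which left 17053 genes. The plan had asked for an RPKM of at least 1 in at least 2 of the 12 libraries. It was first carried over to the tables as at least 2 of the 6, which kept 15550 genes, and all comparisons were run and read in that form. It was then replaced by at least 1 of the 6, after those results had been seen and because genes present in a single table, such as LMO2, were missing from them. The reason given for the replacement is that both libraries of 1 group make up 1 table. The first form is retained as an added alternative, and its effect is given with the other alternatives. The size threshold for counting a gene as higher or lower was a log2 difference of at least 1. The count of such genes is not a count of differences beyond replicate error.

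Genes that were lower or higher in controls later in development formed a falling and a rising class. For each time point the classes were defined from the control values at the other 2 time points, with a log2 difference of at least 1, so that class and comparison share no table. The plan's adjusted p for class membership was dropped. Gene lists (24, fixed before the data were examined) were described by the median log2 difference of their kept members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these tables and is not a p-value. The random lists, also those for the classes, were drawn from the kept genes outside the list or class. In all, 22 lists had at least 5 kept genes. On shuffled differences at 4 hpf over 17053 genes, 0 of 40 simulated lists of 20 genes with no shift lay in the upper 2.5% of random lists, against 17 of 40 with a shift of 0.25, 39 of 40 with 0.5 and 40 of 40 with 1. At 2 hpf 30, 40 and 40 of 40 lists with these shifts were found and at 6 hpf 13, 28 and 40, so a list within the random lists at 6 hpf can still hold a shift of 0.5 or less.

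Symbols came from a table of gene IDs and names that matched 21939 of the 33737 IDs, and 12937 (75.9%) of the kept genes; they are printed as that table gives them, many in capitals. A symbol stands on more than 1 ID for 3305 IDs, and such genes are uncertain where reads could be divided between copies. The genes named in the text follow a rule fixed before the data were examined: ddx3xb and its paralog ddx3xa, the 10 highest and 10 lowest differences per genotype comparison (5 and 5 for changes over time), a symbol that is no clone placeholder, an RPKM of at least 5 in the higher group, and up to 4 members of each list. The parts of the rule that need p-values or single libraries were dropped, and list members were taken by size of difference. The reference gene table at hand is of assembly GRCz12tu, so no coordinates are printed and it was used only to place genes on chromosomes. No genome was used here.

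The alternatives tried were a pseudocount of 0.1, no filter, a minimum RPKM of 5, rescaling by a trimmed mean of log ratios, quantile normalization, a class threshold of 2, and, added after seeing the data, the first form of the filter and a size threshold of 2. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and scipy 1.17.1.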

Results

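RNA from control zebrafish embryos and from embryos mutant for ddx3xb, which encodes a DEAD-box RNA helicase, was compared at 2, 4 and 6 hpf. At 2 hpf the embryo lives on RNA laid down in the egg, by 4 hpf its own genome is being transcribed, and at 6 hpf gastrulation is under way. Each of the 6 combinations of genotype and time was represented by 2 samples and by 1 deposited table of RPKM values, so each value below is the authors' value for a group, without an error or a p-value. The recovered depths of the 12 libraries ran from 37.8 to 73.0 M reads, under the assumption of a plain mean and the step sizes chosen.

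The targeted gene served as a check of the labels, which was clearest at 2 hpf. At 4 and 6 hpf mutant embryos held some of its RNA, so the check was weaker there. ddx3xb (ENSDARG00000005774) stood at an RPKM of 325 in controls and 0.70 in mutants at 2 hpf, a log2 difference of -7.59. At 4 hpf it stood at 318 and 18.8 (-4.01), and at 6 hpf at 194 and 48.8 (-1.97). Mutant embryos thus had ddx3xb RNA at 0.21%, 5.93% and 25.2% of the control level at 2, 4 and 6 hpf. The paralog ddx3xa (ENSDARG00000020573) was close to control at 2 hpf (107 in controls, 97.4 in mutants) and at 4 hpf (117 and 108), and higher in mutants at 6 hpf (32.1 and 118, log2 difference 1.84).

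**Figure D1:**
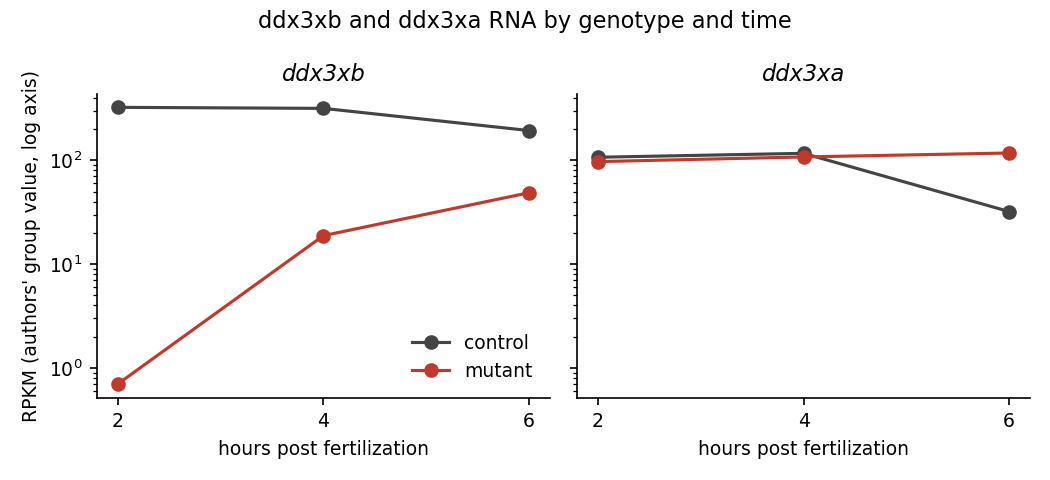
RPKM (log axis) of ddx3xb and ddx3xa against hours post fertilization in control (grey) and mutant (red) embryos; each point is the authors' value for a group, with no error available. In mutants ddx3xb lay at 0.70, 18.8 and 48.8, under the control in each table, and ddx3xa was at 118 against 32.1 in controls at 6 hpf.

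Control embryos gave the course of early development against which the mutant was read. Between 2 and 4 hpf, 1499 of 17053 genes were higher by at least 1 log2 and 484 lower. Genes are ranked here and below only among those with a symbol that is no clone placeholder and an RPKM of at least 5 in the higher group; genes without such a symbol often had larger differences. The 5 largest increases were of inka1a (0.02 to 213), nnr, znf1089, akap12b and aplnrb, an apelin receptor gene. The largest decreases were of sh2d5 (168 to 14.6), ano10b, micall2b, NIBAN2 and SSH2. Between 4 and 6 hpf 2952 genes were higher and 5994 lower. Those that were higher were led by afp4 (1.22 to 673), the keratin gene krt5 (3.32 to 965), fetub and krt99. Those that were lower were led by znf1089 (136 to 2.13), cldnd (852 to 26.2), BTG4, which serves in deadenylation of maternal RNA (200 to 6.16), and nanog, an activator of the zygotic genome (1126 to 39.8). The balance at 6 hpf depended on scaling: with trimmed-mean rescaling 5208 genes were higher and 3323 lower, and with quantile normalization 4024 and 4393.

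Fewer genes passed 1 log2 in mutant embryos in both intervals. Between 2 and 4 hpf 547 genes were higher and 45 lower. znf1089 (0.01 to 62.2), inka1a (0.10 to 58.9), nnr, aplnrb and sult6b1 led the increases, and cox5aa, micall2b, ITM2C, ppdpfb and dip2cb the decreases. Between 4 and 6 hpf 2090 were higher and 3229 lower, or 2988 and 1062 with trimmed-mean rescaling and 2288 and 2128 with quantile normalization. The highest increases there were of ctsll (0.18 to 244), krt4 (3.98 to 860), afp4, SLC7A8 and krt5, and the largest decreases of cldng (781 to 102), sinup, PMS2, ZBTB2 and buc2l. Yet from 4 to 6 hpf the median rise was 2.63 in mutants and 1.37 in controls for early zygotic genes and 2.88 and 1.47 for mesendoderm genes. It was 2.62 and 1.51 for yolk syncytial layer genes and 4.37 and 3.85 for enveloping layer genes. The 95% bootstrap intervals over genes overlapped in each list. The same genes enter both genotypes, however, so that overlap does not bear on the difference. These medians depend on the scaling of the tables, and the difference within genes was not tested. Across kept genes the mutant table at 6 hpf correlated with the control at 4 hpf with Pearson's r = 0.882 and with the control at 6 hpf with r = 0.894, while the 2 control tables correlated with r = 0.723. These are correlations across genes, which are not independent replicates.

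At 2 hpf, before most zygotic transcription, the lists of ribosomal protein and mitochondrially encoded genes had medians above 0 in mutants and those of egg and germ plasm RNAs medians below 0, mostly with differences of less than 1 log2. Polyadenylated RNA was sequenced, so these values cannot tell a difference in the amount of an RNA from one in its poly(A) tail. The 67 ribosomal protein genes had a median log2 difference of 0.91, above all of the random lists, with 27 higher by at least 1 log2 and 1 lower. RPLP0 was at 35.1 in controls and 136 in mutants, RPS2 at 61.7 and 227 and RPLP1 at 33.9 and 126. The 13 mitochondrially encoded genes had a median of 0.60 (0.28 with quantile normalization), with 1 past 1 log2. MT-ND3, just short of 1 log2, was at 998 and 1982. The 18 maternal egg RNAs had a median of -0.34 and the 13 germ plasm RNAs, which mark the future germ cells, one of -0.36, with 2 of 18 and 1 of 13 lower by at least 1 log2 and 0 higher (3 and 2 lower with trimmed-mean rescaling). Without rescaling these were only 2 different genes: DAZL, a germ cell RNA-binding protein gene in both lists, was at 103 and 39.0, and cldnd, a claudin gene, was at 2197 and 865. The 26 cell cycle genes had a median of -0.34, with 1 past 1 log2, WEE1 at 6.04 and 1.85, and CCNB1, which encodes cyclin B1, at 582 and 343. Translation initiation genes had a median of 0.18 (98.95th percentile), with members on both sides: EIF5 was at 77.5 and 33.9 and eif4ebp1, a repressor of cap-dependent translation, at 21.9 and 45.6.

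Single genes stood apart at 2 hpf as well. Of 17053 genes, 706 were higher in mutants by at least 1 log2 and 569 lower, with a median over all genes of 0.01. The 10 lowest named genes were ddx3xb, SSR3, a subunit of the translocon-associated complex (33.1 in controls, 0.11 in mutants), urahb (26.6 and 0.35), ZRANB1, YAE1, NCK1, SMIM13 (49.4 and 2.35), ANKRD33B, ADCY8 and POGLUT3; the symbols ZRANB1, NCK1 and ANKRD33B each stand on more than 1 ID, as do NIBAN2, afp4, ITM2C and ZBTB2 above and SFRP1, MCM6, MDK and GTF3A below. The 10 highest named genes were 1 of the 2 IDs named RRM2 (10.4 and 388), slc52a3-2b (0.41 and 24.8), GNB3 (0.12 and 10.7), pdx1 (2.61 and 33.2), atp5if1a, an inhibitor of the mitochondrial ATP synthase (33.2 and 296), alpk2, fam167aa, col28a1a, tmprss15 and nkx1.2la. RRM2 encodes the small subunit of ribonucleotide reductase; the other RRM2 ID was at 818 and 283, and the sum of both differed by only -0.30 log2.

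Replicate error could be set beside genotype differences only for genes with 20 to 150 reads in both genotypes. That comparison used plain log2 ratios, without the added 1 and without the filter. Its shares therefore do not carry over to the counts given above and below. Over 1310 such genes at 2 hpf, 26.6% differed between mutant and control by at least 1 log2, where the spread between replicate libraries alone would give 14.6%. The shares were 29.2% against 13.0% at 4 hpf (1623 genes) and 35.5% against 15.5% at 6 hpf (1410 genes). On that plain scale, replicate error alone would thus put 13.0% to 15.5% of genes of that level past 1 log2.

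At 4 hpf genes of the early embryonic genome were lower in mutants. Of 26 early zygotic genes 19 were lower by at least 1 log2 and 0 higher, with a median of -1.59, below all of the random lists. polr3gla was at 85.3 in controls and 9.31 in mutants, krt4 at 38.4 and 3.98, the yolk syncytial layer gene mxtx2 at 91.2 and 28.6 and tbx16, a T-box factor of the mesoderm, at 55.1 and 8.91. Enveloping layer genes (13) had a median of -0.93, with krt8 at 27.7 and 3.84 and cldne at 43.1 and 13.8. Yolk syncytial layer genes (9) had a median of -0.96, mesendoderm genes (22) of -0.75, dorsal organizer genes (12) of -0.63 and neuroectoderm genes (9) of -0.62. In these lists 6 of 13, 4 of 9, 7 of 22, 4 of 12 and 3 of 9 genes were lower by at least 1 log2. The lists share members, so with the early zygotic list these are 32 different genes, 11 of them in more than 1 list, and not separate evidence; among lower organizer genes 3 of 4 are in another list. By contrast, the neuroectoderm gene sox19b was higher, at 160 and 341. Its RNA was already at 402 and 409 at 2 hpf and was lower at 4 hpf in both genotypes. It is thus not an exception among genes that rise from 2 to 4 hpf. GSC, the homeobox gene goosecoid, was at 15.6 and 6.96, apela, which encodes a ligand of the apelin receptor, at 25.5 and 6.41, and the organizer gene chrd at 13.8 and 4.28. Among ventral and BMP genes the median was -0.19, inside the range of random lists, though bmp7a was at 11.6 and 0.64. Of the mesendoderm genes 7 were lower by at least 1 log2 and 1 higher, msgn1 at 0.76 and 4.66. At 2 hpf msgn1 was already at 0.29 and 3.35. her1 was at 0.37 and 0.84 at 4 hpf.

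The maternal egg list leaned the other way at 4 hpf, but germ plasm RNAs did not (median 0.01, inside the range of random lists). The egg list had a median of 0.32, with 0 of 18 genes past 1 log2 in either direction and buc, the organizer of germ plasm, at 138 in controls and 246 in mutants. The 6078 genes lower in controls at 6 than at 2 hpf had a median difference of 0.14, with 252 higher and 180 lower by at least 1 log2. The 4108 genes higher in controls at 6 than at 2 hpf had a median of -0.22, with 57 higher and 639 lower. Both medians lay outside the random lists, whose medians were -0.05 and 0.05. Those lists were drawn from genes outside the class, which include the other class, so the 2 results are not separate. Ribosomal protein genes kept a positive median (0.49), with 4 of 67 higher and 1 lower by at least 1 log2. The mitochondrially encoded genes kept a positive median too (0.54), and cell cycle genes a negative one (-0.27), with 3 of 26 lower by at least 1 log2. Of the 2 IDs named MCM6, the minor one was at 11.4 and 2.16 and the other at 125 and 141. Heat shock genes had a median of -0.39, with 1 of 10 past 1 log2, HSPB1 at 102 and 23.9.

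In all, 647 genes were higher and 1076 lower in mutants at 4 hpf. The lowest named genes were ddx3xb, SSR3 (32.0 and 1.74), SMIM13, ZRANB1, stm (35.1 and 3.25), SPAG9, polr3gla, urahb, SFRP1 (23.0 and 1.94) and krt4. The highest named genes were RRM2 (20.7 and 333), GNB3 (0.38 and 10.6), pdx1 (3.95 and 34.7), fam167aa, il13ra2, MRPS12 (2.33 and 17.1), prr15la, slc25a51b, nkx1.2la and alpk2. With both RRM2 IDs summed the difference was -0.26.

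At 6 hpf the lists of maternal egg and germ plasm RNAs had medians above 0 in mutants. Of 18 maternal egg RNAs 14 were higher by at least 1 log2 and 0 lower, with a median of 1.47 (9 and 0 with trimmed-mean rescaling, median 1.18); buc was at 6.13 in controls and 61.7 in mutants, BTG4 at 6.16 and 47.8, GDF9 at 0.69 and 7.68 and cth1, which encodes a zinc finger protein, at 27.9 and 143. Of 13 germ plasm RNAs 10 were higher and 0 lower (median 1.16), or 6 and 1 with rescaling (median 0.79), among them rgs14a (0.48 and 6.01), tdrd7a (3.15 and 14.5) and TDRD6 (2.70 and 9.63). Both lists hold buc, tdrd7a, ca15b and DAZL, so they are not separate evidence. Among genome activators nanog was at 39.8 and 412 and sox19b at 29.7 and 106, while SOX2 was at 97.0 and 20.6. Cell cycle genes went both ways, with 6 of 26 higher and 3 lower, or 4 and 6 with rescaling: WEE2 was at 8.27 and 62.8 and CCNA1 at 32.5 and 211, but CDK1 was lower (log2 difference -1.39).

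Genes of gastrula patterning were divided at 6 hpf. Neuroectoderm genes had a median of -1.53, with 6 of 9 lower by at least 1 log2. Besides SOX2, otx2a was at 62.8 and 14.9 and hoxb1b at 6.02 and 0.08. The gene sox19b was higher, but its RNA fell in controls from 2 to 6 hpf. Ventral and BMP genes had a median of -0.69, with cdx4, a caudal homeobox gene, at 156 and 11.5 and eve1 at 94.9 and 34.0. Enveloping layer genes had a median of -0.68, with krt17 at 78.7 and 13.0. Of 22 mesendoderm genes 4 were higher and 6 lower: mixl1 was at 6.65 and 63.8 and the Nodal ligand gene ndr1 at 1.68 and 12.1, but msgn1 at 125 and 14.0 and pcdh8 at 33.4 and 10.2. Early zygotic genes had 4 members on either side, and the 4 with the largest differences were higher in mutants: mxtx2 (3.58 and 31.6), blf (22.1 and 104), isg15 (26.2 and 99.2) and vgll4l (14.0 and 43.6). In controls these 4 were all higher at 4 than at 6 hpf. Ribosomal protein genes, whose medians lay above 0 at 2 and 4 hpf, had a median of -0.34, with RPLP0 at 610 and 331. Of the 67 genes, 0 were past 1 log2 either way, but 21 were lower with trimmed-mean rescaling (median -0.82). Rescaling also gave 2 mesendoderm genes higher and 10 lower, and 4 early zygotic genes higher and 10 lower. Quantile normalization gave 3 and 7 for mesendoderm genes, but 4 and 1 for early zygotic genes. The 6 lower neuroectoderm genes stayed lower with rescaling, which was fixed in advance because it moved genes downward together at 6 hpf.

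**Figure D2:**
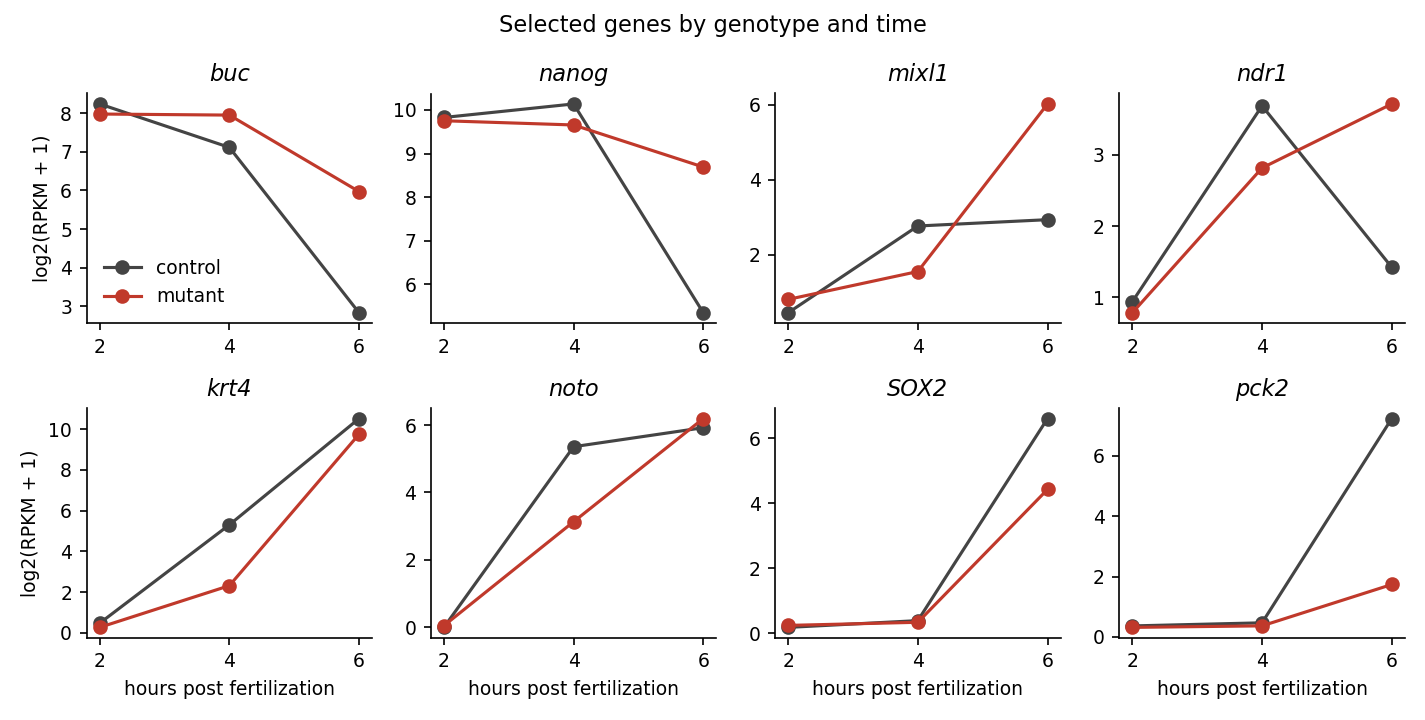
Values of 8 named genes as log2(RPKM + 1) against hours post fertilization in control (grey) and mutant (red) embryos; each point is the authors' value for a group, with no error available. buc (6.13 and 61.7 RPKM at 6 hpf) and nanog (39.8 and 412) were higher in mutants, mixl1 and ndr1 were lower at 4 hpf and higher at 6 hpf, krt4 and noto were lower at 4 hpf, and SOX2 and pck2 were lower at 6 hpf.

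The 484 genes that were lower in controls at 4 than at 2 hpf had a median mutant difference of 0.65 at 6 hpf, with 158 higher and 15 lower by at least 1 log2, against 0.33 for random lists. The 1499 genes that were higher in controls at 4 than at 2 hpf had a median of -0.24, with 166 higher and 262 lower, against 0.26. Over all genes the median was 0.22, and 3114 were higher and 1519 lower. That balance depended on scaling: trimmed-mean rescaling moved the median over all genes by -0.34 and gave 2135 higher and 3193 lower, and quantile normalization gave 2505 and 2430. The class medians kept their signs under both, at 0.33 and -0.66 with rescaling and 0.23 and -0.34 with quantile normalization.

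**Figure D3:**
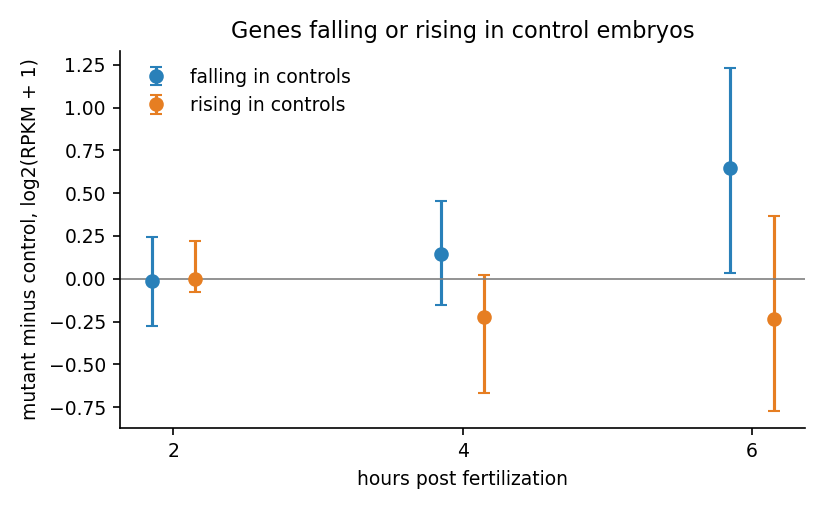
Median mutant minus control difference in log2(RPKM + 1), with the interquartile range over genes as bars, against hours post fertilization, for genes falling (blue) and rising (orange) in controls between the other 2 time points. The medians were -0.01 and 0.00 at 2 hpf, 0.14 and -0.22 at 4 hpf, and 0.65 and -0.24 at 6 hpf.

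The lowest named genes in mutants at 6 hpf were pck2, a gluconeogenic enzyme gene (149 in controls, 2.33 in mutants), the apolipoprotein gene apoa1a (89.2 and 1.57), MDK, slc7a2 (25.1 and 0.13), slc3a2a, metap2a, BHMT (63.8 and 2.16), DPP7, PLA2G12B (93.8 and 5.59) and lmo4a. The highest named genes were RRM2 (10.9 and 319), LMO2 (0.26 and 24.6), col28a1a (0.29 and 24.9), GNB3, caprin2 (3.99 and 57.0), LSM14B (11.8 and 147), HAPLN4, casp23, nanog and TENT5C. With both RRM2 IDs summed the difference was 0.09.

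**Figure D4:**
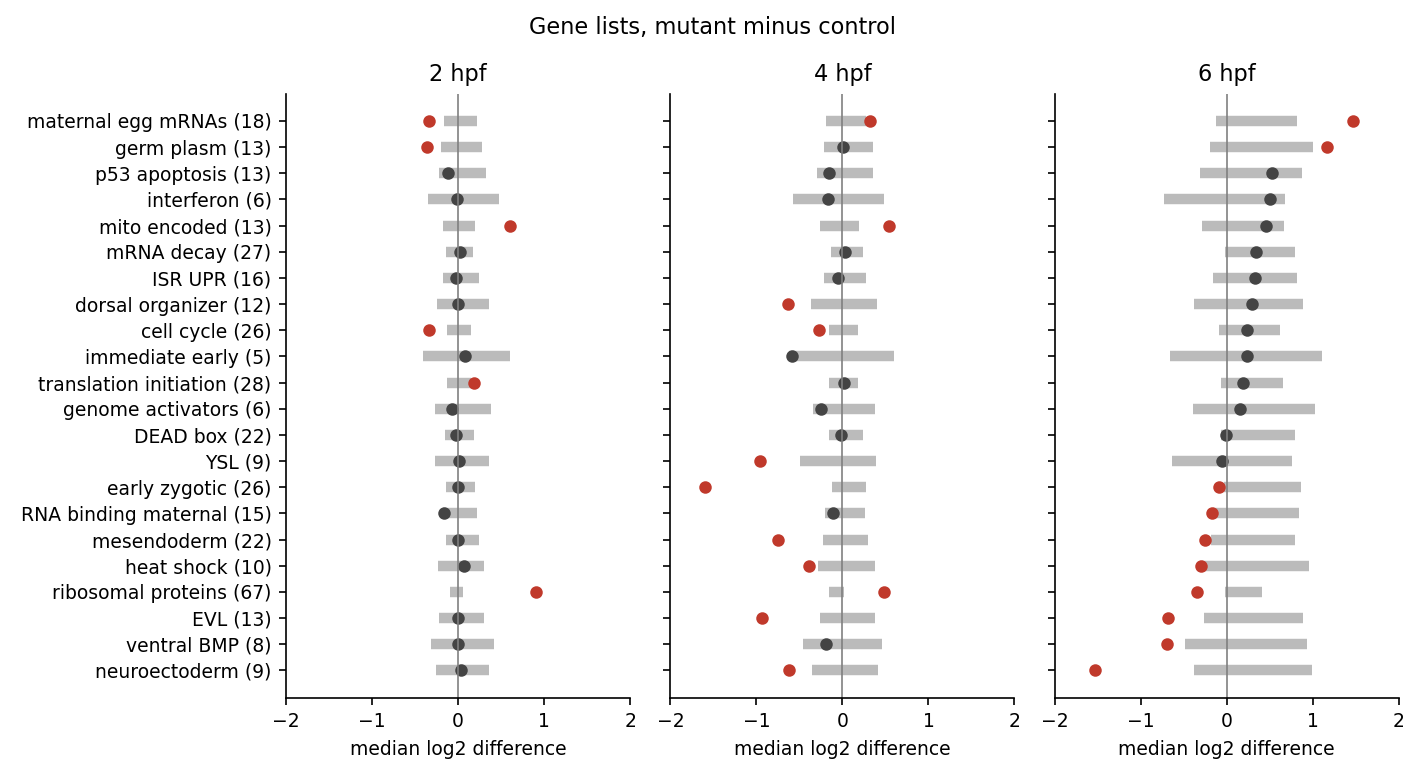
Median mutant minus control difference in log2(RPKM + 1) of 22 gene lists (kept genes in brackets) at 2, 4 and 6 hpf; grey bars span the central 95% of medians of 10000 matched random lists, and red points lie outside them. Early zygotic genes (-1.59) lay lowest at 4 hpf, maternal egg RNAs (1.47) highest and neuroectoderm genes (-1.53) lowest at 6 hpf.

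The genotype difference itself differed between time points, though no test of this was run. From 2 to 4 hpf 235 genes shifted upward in mutants relative to controls by at least 1 log2 and 773 downward. The upward shifts were led by ddx3xb (3.58), TMC1, sh2d5, rasef2 and buc2l, and the downward by HSPB1 (-3.98), krt8 (-3.63), stm, blf and polr3gla. From 4 to 6 hpf 3045 shifted upward and 1396 downward, or 2050 and 2663 with trimmed-mean rescaling and 2421 and 2434 with quantile normalization. mxtx2 (4.47), LMO2, znf1127, mixl1 (4.30) and inka1a led the upward shifts, and pck2 (-5.39), apoa1a, msgn1 (-4.75), MDK and slc3a2a the downward. From 2 to 6 hpf 3077 shifted upward and 1866 downward, or 2139 and 3297 with rescaling and 2530 and 2635 with quantile normalization. ddx3xb (5.62), LMO2, ANKRD33B, caprin2 and GTF3A stood at the top, and pck2, apoa1a, msgn1, MDK and slc3a2a at the bottom.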

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

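All tests of explanations in this part were chosen after the result was seen. Of the gene lists, 3 lay outside the matched random lists on opposite sides of 0 at different time points, and this difference between time points was not tested. Ribosomal protein genes had medians of 0.91 at 2 hpf and 0.49 at 4 hpf, and of -0.34 at 6 hpf. Maternal egg RNAs had a median of -0.34 at 2 hpf, 0.32 at 4 hpf and 1.47 at 6 hpf. Germ plasm RNAs had a median of -0.36 at 2 hpf, 0.01 at 4 hpf (inside the random lists) and 1.16 at 6 hpf. DAZL and ca15b are among the 4 leading members of both of the last 2 lists at 2 hpf, so those are not separate evidence.

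The pattern behind the maternal lists at 4 and 6 hpf is that most genes that change in controls lay between control stages in mutants. A single scaling factor per table is argued against as the whole source. It would shift falling and rising genes together. The medians of the classes defined from controls at 2 and 4 hpf instead had opposite signs at 6 hpf. They lay 0.89 log2 apart (95% bootstrap interval over genes 0.75 to 0.98). Slower loss of maternal RNA alone is argued against too, since early zygotic genes had a median of -1.59 at 4 hpf (95% bootstrap interval -1.96 to -1.15). The differences already there at 2 hpf do not run toward an earlier stage of the mutants. The 3 lists above then differed in the direction in which controls move from 2 to 4 hpf. The medians of that control change were 0.47 for ribosomal protein genes, -0.50 for maternal egg RNAs and -0.79 for germ plasm RNAs. Both comparisons subtract the control values at 2 hpf, however, so error in those values would give matching signs by itself. A control group at an earlier stage at 2 hpf therefore stays open. From 2 to 4 hpf the median change of ribosomal protein genes was 0.09 in mutants and 0.47 in controls, with 0 and 4 of 67 higher by at least 1 log2. From 4 to 6 hpf it was 0.74 and 1.58, with 12 and 56 of 67 higher. This difference between genotypes was not tested, and its first interval shares the values at 2 hpf with the difference seen there.

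Mutant embryos as a whole being at an earlier stage at 4 and 6 hpf, through slower development or collection at a younger age, stays open. For this comparison the genes were chosen by the same control tables that set the scale, unlike the classes above, so noise in a control value can by itself place the mutant between stages. Of the genes changing in controls from 4 to 6 hpf, 5994 falling genes had gone 0.47 of the way from the control value at 4 hpf to that at 6 hpf and 2952 rising genes 0.55, a difference of 0.083, and 90.8% and 82.1% of them lay between the control values. With a class threshold of 2 the positions were 0.42 and 0.64, further apart, and 97.9% and 89.5% lay between. Neither gap is under the 0.05 set for a delay of the whole embryo. These positions were computed without rescaling. The trimmed-mean factors were 1.16 and 0.62 for controls at 4 and 6 hpf and 0.86 for mutants at 6 hpf. Scaling alone could thus place an otherwise unchanged gene between the control values. The position of falling genes at 6 hpf therefore does not separate scaling from a delay. Recovered reads compare replicate libraries for low genes only. They gave the median log2 ratio of the deeper to the shallower library. In mutants at 4 hpf it was -0.16 over 231 genes rising in controls from 4 to 6 hpf. Over 108 falling genes it was 0.15. Over 110 genes rising from 2 to 4 hpf it was -0.03, as over the rest. In mutants at 6 hpf it was 0.08 (rising) and 0.02 (falling from 4 to 6 hpf). Bootstrap intervals over genes do not carry such differences between libraries. Of the genes changing in controls from 2 to 4 hpf, falling genes had gone 0.51 of that way in mutants at 4 hpf and rising genes 0.54 (0.57 and 0.58 with a threshold of 2, over 30 and 525 genes). Likewise, 152 genes that rose by at least 2 log2 from 2 to 4 hpf in controls and then fell by at least 1 had mutant medians of -1.21 at 4 hpf and 0.72 at 6 hpf, with 102 lower and 60 higher by at least 1 log2; choosing genes by a high control value at 4 hpf and a low one at 6 hpf gives such signs in part by itself, so this decides nothing. The gaps at 6 hpf may arise from the shape of each gene's course between 4 and 6 hpf, which was not sampled, so an overall delay and separate changes in zygotic onset and maternal RNA loss cannot be told apart; the genotype itself is the untested biological explanation.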

How the results depend on the processing

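Replicate error is known only for genes with 20 to 150 reads, so a count is called stable here within 1.5 times, a class or list median within its 95% bootstrap interval over genes, and a single gene within 1.5 times. No paired analysis was possible because each table holds 1 value per group and carries no replicate number; leaving out replicates, limma variance models and fits of 2 groups were not run for the same reason. The size threshold of 2 was added after seeing the data, and the filter in use replaced a first form after the results of that form had been seen. Of named-gene values under alternatives, 1751 stayed within 1.5 times and 70 did not, with 0 changes of sign among differences of at least 1 log2. Many of the 1751 could not move, because the filter settings leave the value of a single gene as it is. Among settings that could move a value, 61 moved and 249 stayed with a pseudocount of 0.1. With trimmed-mean rescaling 5 moved and 305 stayed, and with quantile normalization 4 and 306.

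The first form of the filter, an RPKM of at least 1 in at least 2 tables, kept all counts within 1.5 times of those reported: it gave 690 genes higher and 546 lower in mutants at 2 hpf, 638 and 1017 at 4 hpf and 3065 and 1076 at 6 hpf. It moved the rising class to 0.0088 at 2 hpf and -0.29 at 4 hpf. With no filter no count or class median moved. For the genotype and time counts and the classes this was fixed in advance. A gene under an RPKM of 1 in all 6 tables cannot differ by 1 log2 on the scale used. With a minimum of 5, genes lower in mutants numbered 374 at 2 hpf and 965 at 6 hpf, and those shifting downward from 4 to 6 hpf 914, as fewer genes were counted; the rising class was 0.0105 at 2 hpf and -0.29 at 4 hpf and the falling class 0.16 at 4 hpf.

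A pseudocount of 0.1 raised counts because low genes then weigh more. Genes higher and lower in mutants were 1562 and 1172 at 2 hpf, 1312 and 2263 at 4 hpf, and 5178 and 2282 at 6 hpf. From 2 to 4 hpf, 2774 and 767 were higher and lower in controls and 1406 and 170 in mutants, and 4916 were lower in mutants from 4 to 6 hpf. Shifts in the genotype difference were 607 upward and 1795 downward from 2 to 4 hpf, 5300 upward from 4 to 6 hpf and 5011 upward from 2 to 6 hpf. The falling class reversed at 2 hpf, from -0.013 to 0.012, and was 0.18 at 4 hpf and 0.74 at 6 hpf; the rising class was -0.45 and -0.40; ddx3xb was at -8.67 at 2 hpf. For the class reversal the cause was not tested.

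Trimmed-mean rescaling gave 3193 genes lower in mutants at 6 hpf, 5208 higher and 3323 lower in controls and 1062 lower in mutants from 4 to 6 hpf, and 2663 and 3297 downward shifts from 4 to 6 and 2 to 6 hpf. The falling class was -0.061, 0.12 and 0.33 at 2, 4 and 6 hpf and the rising class -0.19 and -0.66 at 4 and 6 hpf. At 6 hpf 2 list medians whose interval excluded 0 reversed, mRNA decay to -0.12 and mitochondrially encoded genes to -0.012; those of genome activators, translation initiation, stress response, immediate early, dorsal organizer and cell cycle genes also became negative, from intervals that included 0. With quantile normalization 2430 genes were lower at 6 hpf, 2128 lower in mutants from 4 to 6 hpf and 2434 shifted downward; the falling class was -0.055 and 0.23 at 2 and 6 hpf and the rising class 0.0082, -0.11 and -0.34 at 2, 4 and 6 hpf. Of genes past 1 log2 from 2 to 4 hpf in controls, 1125 were then higher and 658 lower. The factor of the control table at 6 hpf was 0.62, the lowest; the cause was not tested.

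A class threshold of 2 gave -0.029, 0.21 and 1.04 for the falling class at 2, 4 and 6 hpf and -0.38 and -0.075 for the rising class at 4 and 6 hpf. With a size threshold of 2, genes higher and lower in mutants were 66 and 90 at 2 hpf, 49 and 174 at 4 hpf and 473 and 283 at 6 hpf. The window of 20 to 150 reads for replicate error was a setting of the recovery.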

Other observations

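All tests of explanations in this part were chosen after the result was seen. The remaining gene lists complete the picture at 6 hpf. Genes of p53 signalling and apoptosis had a median of 0.53 (79.8th percentile of random lists). Of these 13 genes, 4 were higher and 1 lower by at least 1 log2, or 3 and 3 with trimmed-mean rescaling (median 0.08). Among the higher ones CASP9 was at 2.00 in controls and 6.88 in mutants, cdkn1a at 2.21 and 9.62 and mdm2 at 23.4 and 53.6. Heat shock genes had a median of -0.30, with HSPB1 at 1686 and 717 and hsp70.3 at 8.83 and 3.33. Integrated stress and unfolded protein response genes went both ways (median 0.33), with DDIT3 at 7.37 and 1.81 and HSP90B1 at 27.2 and 72.9. Genes of mRNA decay had a median of 0.34, genome activators 0.15, immediate early genes 0.24, interferon genes 0.51, dorsal organizer genes 0.29, yolk syncytial layer genes -0.06, translation initiation genes 0.19, cell cycle genes 0.24 and mitochondrially encoded genes 0.46. All of these lay within the random lists except heat shock genes, and all but those of p53, interferon, heat shock and yolk syncytial layer genes turn negative with trimmed-mean rescaling. DEAD-box genes had a median of -0.01, but besides ddx3xa the germ cell gene DDX4 was at 41.8 and 120. Maternal RNA-binding protein genes had a median of -0.17, in the lowest 2.5% of random lists, although PABPC1L was at 7.92 and 23.4; quantile normalization turned that median to 0.13.

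Markers of later tissues and of ovarian follicle were nearly all below the filter, with 3 of 13 and 1 of 7 matched genes kept. The transferrin gene tfa was at 68.6 in controls and 4.57 in mutants at 6 hpf and the actin gene actc1a at 4.68 and 0.32. CYP17A1, a steroid hydroxylase gene of the follicle list, was at 76.5 and 69.2 at 2 hpf and 2.71 and 27.7 at 6 hpf. The mitochondrially encoded share of summed RPKM was 7.09% in controls and 10.9% in mutants at 6 hpf.

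The second pattern is the return of ddx3xb RNA in mutant embryos, from 0.21% of control at 2 hpf to 5.93% and 25.2% at 4 and 6 hpf. Reads from the paralog ddx3xa are argued against, since ddx3xb amounted to 0.72% of ddx3xa in mutants at 2 hpf and to 41.4% at 6 hpf. Control RNA mixed into the mutant libraries stays open at 4 hpf. It was checked on 23 other genes at or under 5% of control in mutants at 2 hpf (control RPKM of at least 10). The 17 still at 10 or more in controls at 4 hpf had a median of 7.71% of control, with a range of 3.25% to 177%. Of these, 0 lay under 0.5 times the ddx3xb share, the limit set for the check. A mixture as the whole source would put each gene at the ddx3xb share or above, and 5 of the 17 lay under it. The check therefore does not decide at 4 hpf. At 6 hpf a mixture is argued against as the whole source: the 8 such genes had a median of 10.6%, and 5 lay under 0.5 times 25.2%, among them urahb at 5.57% and SMIM13 at 8.68%. Transcription from the embryo's own genome stays open and untested, at both times.

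The third pattern is a set of 271 genes shifted the same way by at least 1 log2 at all 3 times, 187 higher and 84 lower in mutants. Between 2 and 4 hpf alone, 369 higher genes were shared where independent lists would share 26.8, and 311 lower genes against 35.9. Linkage to ddx3xb is argued against for the 112 that could be placed by symbol, of which 3 (2.68%, 95% Wilson interval 0.92% to 7.58%) lie on its chromosome, which holds 4.25% of all placed genes. It cannot be told apart for the other 158, since only 41.5% were placed. For RRM2, reads divided between its 2 IDs are a candidate explanation: the sum of both differed by -0.30 log2 at 2 hpf, -0.26 at 4 hpf and 0.09 at 6 hpf. Genetic background of the mutant line, which could act through variants that alter read mapping as well as through expression, was not tested.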
